A study of Mus musculus with 6 samples.

How the data were processed

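Gene expression was measured by RNA sequencing in 6 libraries of hippocampal neurospheres, 3 labelled CTRL and 3 labelled FGF13cko. Libraries were made with the NEBNext Ultra RNA kit and sequenced on an Illumina instrument, per the labels' protocols. That kit does not mark the strand of a read, so reads of overlapping genes on opposite strands cannot be told apart. STAR, DESeq2 and the mouse build mm10 are named in the submitters' processing notes, without versions. The gene annotation and the counting tool are not given in the sources used here.

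The deposited table holds 54532 gene rows with 1 normalized expression value per library. These values are a signal on the scale of read counts: the authors deposited gene counts divided by a size factor per library. Each library's values were whole multiples of 1 step, and dividing by that step gave whole reads for 100% of the values within 0.01 of a read. Size factors recomputed from these reads differed from the recovered ones by at most 6e-05. The same table holds the authors' deposited log2 fold change with its standard error, the Wald statistic as a score, and the p-value and adjusted p-value for FGF13cko against CTRL. It holds no per-library column of another series. Recovered reads summed to 24112509, 24261454 and 22191718 in CTRL 1, 2 and 3, and to 24531400, 24233142 and 24015697 in FGF13cko 1, 2 and 3. A count of 0 allows up to 3 reads at the 95% level, which is 2.89 to 3.05 normalized counts in these libraries. Such limits and the ratio intervals cover counting error only, since reads are not independent molecules.

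GENCODE release M21 (GRCm38, the same assembly as mm10) gave coordinates for 54495 of the gene IDs, and coordinates are 1-based. Where several IDs carried 1 symbol, the ID with the highest mean was used for lists and names.

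The values are not raw counts, so the main test was limma (version 3.58.1, R 4.3.3) on log2(normalized count + 1), with genotype as the only term and a mean-variance trend. Genes with a mean of at least 10 over the 6 libraries were tested, 16852 in all. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The count tests edgeR (quasi-likelihood, version 4.0.16) and DESeq2 (Wald, version 1.42.0) were run on the recovered reads as alternatives. Fgf13 was also compared by an exact permutation test over the 20 assignments of 3 and 3 libraries. Gene lists were compared with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, and were adjusted over the lists. All of the 12 list calls were lost with an estimated correlation. By fry's directional test, which asks whether the members move one way on balance and compares no list with other genes, 6 lists passed (adjusted p = 0.0419 each). Of the 12 camera calls these include 4, hypoxia and glycolysis, Notch, sodium channels, and microglia and macrophage. The other two, neural stem cell, and mural and fibroblast, were not camera calls, and the remaining 8 camera calls did not pass it. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

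The groups, the tests, 35 gene lists and most alternatives were fixed before the data were examined. Of the 35 lists, 1 (genes that mark sex) served as a check of the labels, 1 (erythroid) had too few tested members, and 33 were tested. Named genes were 11 fixed in advance, and the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 50 and no overlap between the groups, leaving out predicted gene models. From each list past the camera test, up to 2 members that rose and 2 that fell with the smallest adjusted p were named, and from each other list with a member past the threshold, 1 member. This gave 67 genes, of which 3 are not reported here. The full set of hypoxia members that fell was named after their values were seen.

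Whether the shared replicate numbers pair the libraries was checked from residuals around the group means. Same-numbered libraries correlated at 0.36, 0.20 and 0.54 for replicates 1, 2 and 3, all above 0.1, and no label says what a number marks. Group residuals sum to 0, so replicate 3 libraries that stand apart alike in both groups raise every correlation between replicates 1 and 2. CTRL 1 correlated at 0.26 with FGF13cko 2, and CTRL 2 more with FGF13cko 1 (0.33) than with FGF13cko 2. The values therefore match the replicate 3 libraries but do not show which of replicates 1 and 2 belong together. A fit with the replicate number as a block was run beside each result, as an alternative whose pairing was taken from these same data. No libraries of 1 group agreed within sampling noise: the chi-square per gene was 8.63 for CTRL 1 against 2, 12.8 for FGF13cko 1 against 2, and 48.9 to 165 for pairs with a replicate 3 library. The labels do not say that each library came from a separate mouse, so p-values measure only the spread between these libraries.

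The limma step was tested on simulated data for 3 against 3 libraries with the means and dispersions of 16895 genes, 200 of them changed. It recovered 3.0% of genes changed 1.5-fold, 43.3% of those changed 2-fold and 93.9% of those changed 4-fold, with 12 false calls. DESeq2 recovered 7.5%, 80.6% and 97.0%, with 58 false calls. A gene changed by less than 2-fold was therefore often missed at this size. The changed genes were drawn from those with a mean of at least 50, although genes down to a mean of 10 were tested. Counts were simulated gene by gene, without correlation between genes or a shift shared by the replicate 3 libraries. The false calls therefore may not describe the real data. Other alternatives were the pseudocount, the filter on low values, 3 other scalings, leaving out each library, robust and weighted limma fits, and, added after the data were seen, leaving out both replicate 3 libraries and edgeR with the block.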

Results

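Bulk RNA sequencing measured gene expression in neurospheres, floating spheres of dividing neural progenitor cells, grown from the hippocampus of newborn (postnatal day 0) C57BL/6 mice. Cells of 1 mouse were plated in 2 wells with the growth factors FGF-2 and EGF (20 ng/ml each), and the spheres were collected on day 7 of culture. The 6 libraries fall into 2 groups of 3. The CTRL group is labelled as carrying hGFAPCre, a Cre recombinase transgene driven by the human GFAP promoter, with an intact Fgf13 gene on the single X chromosome. The FGF13cko group is labelled with the same transgene and a floxed Fgf13 gene. Reads assigned to genes ranged from 22191718 to 24531400 per library. The comparison asks which genes differ between neurospheres with and without conditional deletion of Fgf13, and the controls are described as littermates.

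Fgf13 (ENSMUSG00000031137, chromosome X, 59062145 to 59568071, minus strand, GRCm38), the targeted gene, encodes a member of the intracellular FGF homologous factors, which are not secreted. Its normalized counts were 480, 651 and 276 in CTRL replicates 1, 2 and 3, and 201, 239 and 332 in FGF13cko replicates 1, 2 and 3. The means were 469 ± 188 and 257 ± 67.8 (SD, n = 3 each), a log2 change of -0.81 (SE 0.33) that did not pass the test (limma adjusted p = 0.134). CTRL 3 lay inside the range of the FGF13cko libraries, so the counts over the whole gene did not separate the groups. An exact permutation test, 2-sided, gave p = 0.2, where 0.1 is the smallest value that 3 against 3 allows. Without CTRL 3 the change was -1.15 (limma adjusted p = 0.0108), and with each other library left out in turn it did not pass. Counts over a whole gene do not show which exon is missing, so they check the deletion only in part.

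Of the 3 related intracellular FGF genes, Fgf11 (chromosome 11, 69796068 to 69801857) fell from 3884 ± 554 to 555 ± 110 normalized counts, a log2 change of -2.81 (SE 0.19, limma adjusted p = 0.00115). Fgf12 was at 298 ± 20.3 in CTRL and 409 ± 82.7 in FGF13cko, and Fgf14 at 156 ± 17.7 and 225 ± 15.9. Neither passed the test (limma adjusted p = 0.145 and 0.0837), although their values did not overlap between the groups. Without CTRL 3, Fgf14 passed (log2 change 0.58, limma adjusted p = 0.0441).

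**Figure D1:**
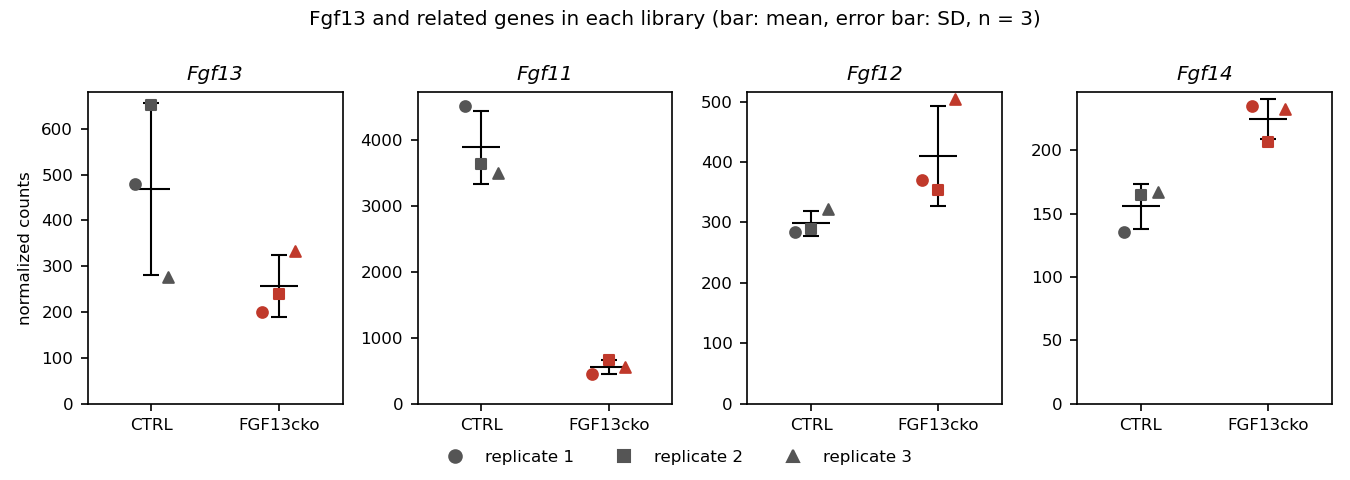
Normalized counts (vertical axis, from 0) of Fgf13, Fgf11, Fgf12 and Fgf14 in each CTRL and FGF13cko library; symbols mark the replicate number, horizontal bars the mean and error bars the SD (n = 3). Fgf13 overlaps between the groups, with CTRL 3 at 276 and FGF13cko 3 at 332, while Fgf11 lies near 3884 in CTRL and near 555 in FGF13cko.

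Genes of low-oxygen response and sugar breakdown were lower in FGF13cko, genes of young neurons were higher, and genes of the Notch pathway and of mitosis were lower. These are 4 of the 12 list calls made by camera with a preset correlation, and each was lost with an estimated correlation (adjusted p = 0.638). The young neuron and mitosis lists also did not pass fry's directional test (adjusted p = 0.102 and 0.151). Over the whole transcriptome, 2465 of 16852 tested genes passed the test (limma, adjusted p under 0.05), 1272 higher and 1193 lower in FGF13cko. The values of all 2465 were without overlap between the groups. Among all tested genes 6637 (39.4%) had no overlap. Chance gives 10% on average over groupings, but genes that vary together can move this share far in any 1 grouping. Of the genes past the test, 1472 changed by 2-fold or more. With the replicate number as a block, 5064 genes passed (2723 higher, 2341 lower). The authors' deposited table has 3444 genes under the same threshold, of 20641 with an adjusted p, 1812 higher and 1632 lower.

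The first principal component held 53.3% of the variance and parted the genotypes, and the second held 31.3% and set both replicate 3 libraries apart from the others of their groups. The share of reads from mitochondrially encoded genes was 4.14% in CTRL 3 and 4.05% in FGF13cko 3, against 1.48% and 1.46% in the other CTRL and 2.28% and 2.36% in the other FGF13cko libraries. Single libraries moved the count of genes. It was 732 without CTRL 1, 1571 without CTRL 2 and 4373 without CTRL 3. It was 1408, 469 and 923 without FGF13cko 1, 2 and 3, and 6145 without both replicate 3 libraries.

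**Figure D2:**
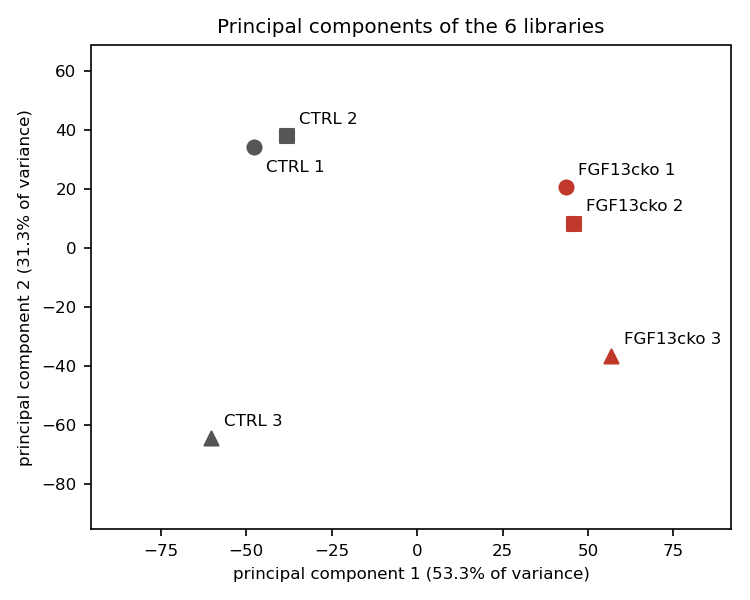
Scores of the 6 libraries on the first (horizontal axis, 53.3% of variance) and second (vertical axis, 31.3%) principal components of the log2 values; colour marks the genotype and symbol the replicate number. The genotypes lie on opposite sides of the first component, and CTRL 3 and FGF13cko 3 lie lowest on the second.

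The gene group with the largest fall was hypoxia and glycolysis, where 13 of 21 members fell and none rose (17 fell when adjusted over the list alone). The list median was -1.38 on the log2 scale (camera adjusted p = 4.06e-11; adjusted p = 0.638 with an estimated correlation). Vegfa (chromosome 17, 46016993 to 46032369), the main angiogenic growth factor induced by low oxygen, fell from 68295 ± 6790 to 6461 ± 2475 normalized counts (log2 change -3.47, SE 0.28, limma adjusted p = 0.00118). Bnip3, a mitochondrial protein of mitophagy that is also induced by low oxygen, fell from 2574 ± 324 to 365 ± 100 (log2 change -2.84, SE 0.21, limma adjusted p = 0.00115). The other members that fell were Pdk1, Ankrd37, Tpi1, Pgk1, Pfkl, Car9, Ldha, Pfkp, Egln3, Hk2 and Pgam1, most of them glycolytic enzymes or regulators of pyruvate use and oxygen sensing. Relative to the CTRL mean, the list median was -1.33, -1.33 and -1.70 in FGF13cko 1, 2 and 3, and -0.53 in CTRL 3. Leaving out 1 library gave 8 changed members (without CTRL 1, FGF13cko 2 or FGF13cko 3), 9 (without CTRL 2 or FGF13cko 1) or 21 (without CTRL 3).

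Neuronal genes moved the other way. In the young neuron list 10 of 20 members rose and none fell (14 rose adjusted over the list alone; median log2 change 0.99, camera adjusted p = 4.21e-05; adjusted p = 0.638 with an estimated correlation). Doublecortin (Dcx), a microtubule protein of newborn neurons, rose from 1644 ± 158 to 4092 ± 1453 normalized counts (log2 change 1.26, SE 0.25, limma adjusted p = 0.0169). Neurod1 (chromosome 2, 79452521 to 79456751), a transcription factor of neuronal differentiation, rose from 207 ± 63.0 to 744 ± 228 (log2 change 1.85, SE 0.30, limma adjusted p = 0.00883). It is not a young neuron member but belongs to the intermediate progenitor list, where 3 of 16 members rose and 4 fell (camera adjusted p = 0.78). The neurofilament genes Nefm and Nefl rose by 1.75 (SE 0.23) and 2.30 (SE 0.37) on the log2 scale. They overlap on opposite strands, and the library kit does not mark strand, so part of their reads cannot be told apart. Microtubule regulators and tubulins had 5 of 17 members higher (5 adjusted over the list alone, 8 with the replicate block; median 0.49, camera adjusted p = 0.00347; adjusted p = 0.659 with an estimated correlation). Of these 5, Dcx, Stmn2 and Tubb3 are also among the 10 young neuron members that rose, so the lists are not separate evidence. The other two were the kinesin heavy chain Kif5c, from 1856 ± 428 to 4626 ± 1171, and Map1b, from 4831 ± 1347 to 12068 ± 2239. Voltage-gated sodium channels had 5 of 9 members higher and none lower (7 adjusted over the list alone; median 1.07, camera adjusted p = 0.000349; adjusted p = 0.638 with an estimated correlation). Scn2b, an auxiliary subunit, went from 48.9 ± 9.75 to 157 ± 42.2. Scn4b rested on 4 reads in CTRL and 87 in FGF13cko, a ratio of 20.9 (95% counting interval 7.87 to 78.4).

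Many of these calls were lost without FGF13cko 2, where the count over all genes fell as well (469 against 2465). Without that library 1 young neuron, 0 microtubule and 1 sodium channel member passed, and the limma adjusted p of Neurod1, Nefl, Scn2b, Kif5c, Map1b and Dcx lay between 0.0525 and 0.0772. Their log2 changes stayed near those of all 6 libraries, at 1.86, 2.26, 1.69, 1.29, 1.27 and 1.26 in that order, against 1.85, 2.30, 1.65, 1.31, 1.34 and 1.26. Young neuron members numbered 2 without CTRL 1, and Dcx then had a limma adjusted p of 0.0664. Without FGF13cko 3, young neuron members numbered 5, microtubule members 1 and sodium channel members 3, with Kif5c and Map1b at limma adjusted p of 0.0517 and 0.0579. Microtubule members numbered 2 without CTRL 1, and the young neuron list median per FGF13cko library was 0.43, 0.96 and 1.56.

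Genes of inhibitory (GABAergic) neurons and their precursors also differed, with 7 of 16 members higher and 1 lower (10 higher and 1 lower adjusted over the list alone; median 1.60, camera adjusted p = 0.000231; adjusted p = 0.638 with an estimated correlation). Sp9, a transcription factor of the lineage, rose from 58.6 ± 13.5 to 323 ± 75.4 normalized counts (log2 change 2.44, SE 0.26, limma adjusted p = 0.0024). Its annotation overlaps Cir1. Dlx2 rose from 20.6 ± 4.60 to 70.4 ± 33.0, whereas Gsx2, a factor of ventral progenitors, fell from 53.6 ± 7.47 to 12.3 ± 1.05. FGF13cko 3 stood apart here, with a list median of 2.30 against 0.89 and 0.78 in FGF13cko 1 and 2. The replicate block gave 13 higher and 1 lower. Members past the test numbered 2 without CTRL 1, CTRL 2 or FGF13cko 2, 3 without FGF13cko 3 and 4 without FGF13cko 1, and Dlx2 was lost in the first 3 of these fits and in that without FGF13cko 3 (limma adjusted p = 0.0761 to 0.112).

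Notch pathway genes fell on balance, with 6 of 16 members lower and 1 higher (the same numbers adjusted over the list alone; median -0.38, camera adjusted p = 0.0115; adjusted p = 0.638 with an estimated correlation). Dll3, an inhibitory Notch ligand of neurogenic progenitors, fell from 1117 ± 272 to 220 ± 27.5 normalized counts (log2 change -2.32, SE 0.21, limma adjusted p = 0.00159). The Notch target Hey2 fell from 95.4 ± 7.50 to 24.3 ± 1.93, while the ligand Jag1 rose from 1234 ± 420 to 3764 ± 84.2. These 3 genes passed with each library left out in turn. In the G2/M list 7 of 24 members fell and none rose (14 fell adjusted over the list alone, 20 with the replicate block; median -0.65, camera adjusted p = 5.04e-07; adjusted p = 0.638 with an estimated correlation). Relative to the CTRL mean, the list median was -0.20 in CTRL 3, level with -0.21 in FGF13cko 1, against -0.70 and -1.06 in FGF13cko 2 and 3. Cyclin B2 (Ccnb2) went from 2234 ± 236 to 1150 ± 252 and Hmmr from 2527 ± 79.1 to 1387 ± 323. Mki67, the usual proliferation marker, was at 11683 ± 3397 in CTRL and 8218 ± 2815 in FGF13cko and did not pass (log2 change -0.52, limma adjusted p = 0.291; 0.0299 with the replicate block). No G2/M member passed without FGF13cko 2 or FGF13cko 3, 1 passed without CTRL 1, 2 without CTRL 2, 11 without FGF13cko 1 and 16 without CTRL 3. Ccnb2 and Hmmr then missed the threshold without CTRL 1, FGF13cko 2 or FGF13cko 3 (limma adjusted p = 0.0515 to 0.0904), and Hmmr also without CTRL 2 (0.0528). G1/S and DNA replication genes did not change as a list, with 0 of 25 members past the test by limma and 3 with the replicate block (camera adjusted p = 0.563).

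Markers of neural stem cells were lower for 5 of 19 members (5 adjusted over the list alone, with 4 higher and 6 lower under the replicate block), and the list itself did not pass by camera (median -0.25, adjusted p = 0.0682; adjusted p = 0.638 with an estimated correlation), while it passed fry's directional test (adjusted p = 0.0419). Sox2 (chromosome 3, 34650405 to 34652461), a core stem cell transcription factor, fell from 11372 ± 693 to 6606 ± 617 normalized counts (log2 change -0.79, SE 0.15, limma adjusted p = 0.0152). Sox2 lies inside the noncoding gene Sox2ot, whose reads cannot be separated here. Nestin (Nes) was at 13216 ± 7930 and 27507 ± 7653 and did not pass (log2 change 1.29, limma adjusted p = 0.149; 0.00609 with the replicate block). CTRL 3 was low in Nes, at 4155 against 16604 and 18888 in CTRL 1 and 2, and without it the log2 change was 0.59 and did not pass. Without both replicate 3 libraries, a fit added after the data were seen, it was 0.84 and passed (limma adjusted p = 0.000206). Gfap, at 12199 ± 12607 and 17700 ± 11875, was highest in both replicate 3 libraries (26687 and 30885) and did not pass (log2 change 0.83, limma adjusted p = 0.472; 1.66 and 0.0390 without CTRL 3, 1.15 and 0.0088 without both replicate 3 libraries). Over the fits run, the log2 change of Gfap ranged from 0.24 to 1.66. Members past the test numbered 2 without CTRL 1 or FGF13cko 2, 3 without FGF13cko 3 and 9 without CTRL 3, and Sox2 missed the threshold in the first 3 of these fits (limma adjusted p = 0.0638 to 0.0772).

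In the oligodendrocyte lineage 3 of 16 members fell and none rose (5 fell adjusted over the list alone, 9 with the replicate block; median -0.94, camera adjusted p = 0.00147; adjusted p = 0.638 with an estimated correlation). Gpr17, a receptor of committed precursors, fell from 2394 ± 1666 to 389 ± 134 normalized counts, with CTRL 3 at 4305 and Lims2 overlapping the gene. Sox10, a lineage transcription factor, fell from 3201 ± 1560 to 861 ± 283. Without FGF13cko 2 no member of the list passed (limma adjusted p = 0.0665 for Gpr17 and 0.0731 for Sox10), 2 passed without CTRL 1, FGF13cko 1 or FGF13cko 3, and 6 without CTRL 3. Relative to the CTRL mean, the list median was 0.75 in CTRL 3, against -0.34 and -0.56 in CTRL 1 and 2.

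The microglia and macrophage, interferon response and extracellular matrix lists were higher in FGF13cko by camera with the preset correlation. In the microglia and macrophage list 3 of 13 members rose and none fell (5 rose adjusted over the list alone and 5 with the replicate block; median 1.19, camera adjusted p = 0.00301; adjusted p = 0.638 with an estimated correlation). The lysosomal gene Cd68 rose from 79.6 ± 11.4 to 203 ± 20.5 normalized counts and Fcer1g, an immune receptor subunit, from 20.9 ± 4.78 to 51.2 ± 1.89. No member passed without FGF13cko 2 (Cd68 at limma adjusted p = 0.0523), 1 passed without CTRL 1, CTRL 2 or FGF13cko 1, 6 without CTRL 3, and Fcer1g missed the threshold with any library but CTRL 3 left out (limma adjusted p = 0.0527 to 0.112) and without the filter on low values (0.0544). In the interferon response list 5 of 21 members rose (7 adjusted over the list alone, 15 with the replicate block; median 1.27, camera adjusted p = 0.000599; adjusted p = 0.659 with an estimated correlation). Gbp3, an interferon-induced GTPase, rose from 290.5 ± 170 to 1252 ± 554, and Oas1a rested on 3 reads in CTRL and 64 in FGF13cko, a ratio of 20.5 (95% counting interval 6.70 to 102). Both replicate 3 libraries were high in this list, with medians of 0.97 in CTRL 3 and 2.28 in FGF13cko 3 against 0.52 and 0.89 in FGF13cko 1 and 2. No interferon member passed without CTRL 1, FGF13cko 2 or FGF13cko 3, where Gbp3 was at a limma adjusted p of 0.0565 to 0.0572 and Oas1a at 0.0583 and 0.0628 without CTRL 1 and FGF13cko 2 and too low to be tested without FGF13cko 3. Interferon members numbered 2 without CTRL 2 and 14 without CTRL 3.

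In the extracellular matrix and adhesion list 7 of 21 members rose and 1 fell (8 and 1 adjusted over the list alone; median 0.58, camera adjusted p = 0.00957; adjusted p = 0.638 with an estimated correlation). Sparc, a secreted matrix-binding protein, rose from 2293 ± 327 to 6171 ± 522 normalized counts (log2 change 1.43, SE 0.16, limma adjusted p = 0.00269), and the matrix protease gene Mmp2 from 338 ± 93.6 to 907 ± 123. Fibronectin (Fn1) went against the list and fell from 5631 ± 1381 to 2073 ± 685. Members past the test numbered 2 without FGF13cko 2 (Mmp2 at limma adjusted p = 0.0543), 3 without FGF13cko 3 and 4 without CTRL 1, and Fn1 missed the threshold in the last pair (limma adjusted p = 0.052 and 0.0598).

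Cytosolic ribosomal protein genes were lower as a list by a small amount (median -0.52, camera adjusted p = 3.93e-05; adjusted p = 0.638 with an estimated correlation). Relative to the CTRL mean, CTRL 3 stood apart at a list median of 0.40, against -0.21 and -0.20 in CTRL 1 and 2 and -0.49, -0.72 and -0.37 in FGF13cko 1, 2 and 3. Only Rpl3 of 25 members passed over all genes, from 42274 ± 6900 to 24265 ± 1884 normalized counts (limma adjusted p = 0.0378), none passed adjusted over the list alone, and 15 fell with the replicate block. Rpl3 overlaps Syngr1 and the small nucleolar RNA gene Snord43, and it missed the threshold with any library but CTRL 3 left out (limma adjusted p = 0.0737 to 0.164). It also missed it without the filter on low values (0.0801), and without CTRL 3, 5 members passed. The mitochondrially encoded list did not pass (median 0.70, camera adjusted p = 0.0604; 0.0083 with the replicate block, and adjusted p = 0.743 with the block and an estimated correlation), and mt-Nd2 alone of 11 members rose (2 adjusted over the list alone, 6 with the replicate block), from 20247 ± 6903 to 55980 ± 15513. Without CTRL 1, CTRL 2, FGF13cko 2 or FGF13cko 3, mt-Nd2 missed the threshold (limma adjusted p = 0.0549 to 0.0742), and 7 members passed without CTRL 3.

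**Figure D3:**
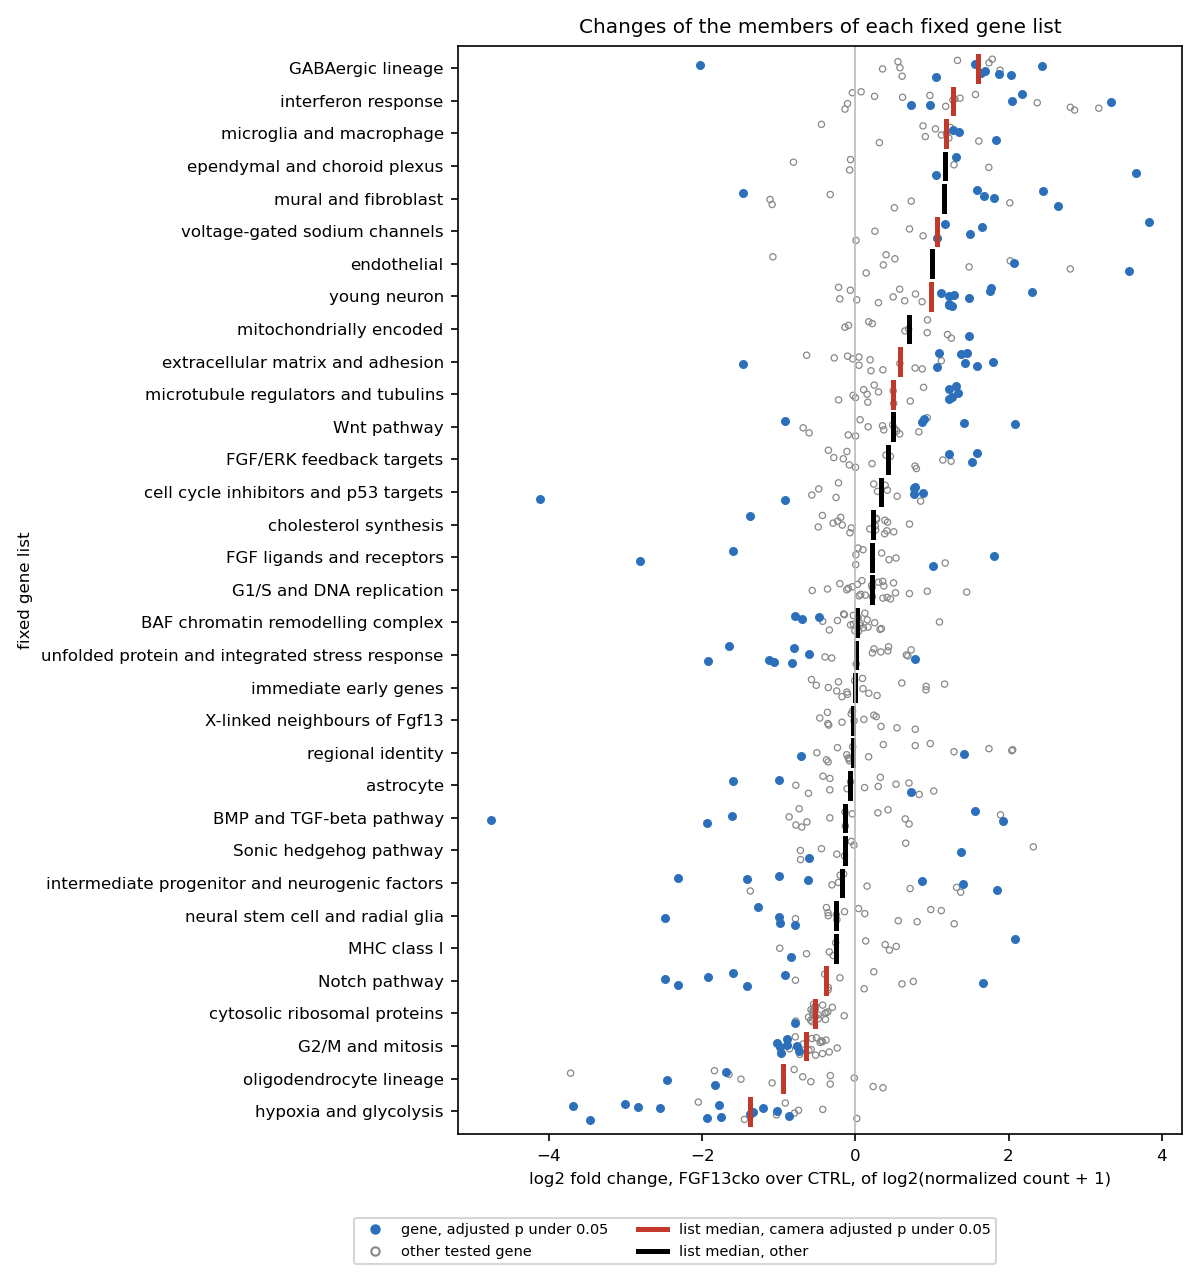
Log2 change, FGF13cko over CTRL, of the tested members of each fixed gene list (horizontal axis); each point is a gene, filled where its limma adjusted p is under 0.05, and each vertical bar is the list median, red where the camera adjusted p is under 0.05 with the preset correlation. Hypoxia and glycolysis has the lowest median (-1.38) and the GABAergic lineage the highest (1.60).

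Of the single genes with the largest rises, Prm1 (chromosome 16, 10796326 to 10805839), which encodes the sperm chromatin protein protamine 1, went from 6.41 ± 3.56 to 1722 ± 637 normalized counts. This rested on 19 reads in CTRL and 5326 in FGF13cko, a ratio of 269 (95% counting interval 172 to 448; limma adjusted p = 0.000812). Esm1, an endothelial proteoglycan gene, rose from 9.77 ± 4.73 to 163 ± 34.2, the serpin gene Serpinb5 from 7.41 ± 1.51 to 104 ± 19.3, and Pex5l from 44.2 ± 11.6 to 408 ± 64.2. The matrix gene Thbs2 rose from 109 ± 22.5 to 1008 ± 353, the retinoic acid synthesis gene Aldh1a3 from 60.4 ± 30.4 to 482 ± 66.1, and the vitamin D catabolic gene Cyp24a1, which overlaps Pfdn4, from 23.6 ± 7.73 to 213 ± 62.8. Steap4 had the second largest rise, but its FGF13cko libraries held 105, 48.2 and 613 normalized counts, and it missed the threshold with any library but CTRL 3 left out (limma adjusted p = 0.0677 to 0.105). Its adjusted p was 0.0574 by DESeq2 and 0.247 in the authors' deposited table.

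The largest falls included Ndufa4l2 (chromosome 10, 127514967 to 127517154), a mitochondrial gene induced by low oxygen, from 617 ± 252 to 21 ± 12.7 normalized counts (log2 change -4.85, SE 0.46, limma adjusted p = 0.00192); its annotation overlaps Shmt2. Cdkn1c (chromosome 7, 143458339 to 143461050), an imprinted inhibitor of the cell cycle, fell from 569 ± 71.8 to 32.7 ± 10.8 (log2 change -4.12, SE 0.28, limma adjusted p = 0.00115). Selenbp1 fell from 1756 ± 579 to 96.0 ± 27.2, Mgarp from 669 ± 133 to 45.9 ± 32.3, the mucin gene Muc2 from 408 ± 109 to 27.5 ± 24.2, Fam71f2 from 313 ± 121 to 23 ± 8.66, and Tnfrsf13c, the BAFF receptor of B cells, from 216 ± 96.7 to 9.05 ± 2.89. Bmp4, a secreted signalling protein, was at 44.8, 25.2 and 559 in CTRL 1, 2 and 3 and at 0.984, 0.965 and 7.73 in FGF13cko 1, 2 and 3. It missed the threshold without CTRL 1 or any one FGF13cko library (limma adjusted p = 0.0523 to 0.118). The limma log2 change was -4.76 (SE 1.13, adjusted p = 0.0299). The authors' deposited table gives a log2 change of -1.18 and an adjusted p of 0.0561, which does not pass. In the fits run here the log2 change of Bmp4 lay between -6.04 and -3.42, and Bmp4 kept its call by DESeq2 on the recovered reads. The deposited change of Steap4, whose limma SE was 1.29, is also far smaller, at 0.706 against 4.92 by DESeq2 here. Those of Fgf11 (-2.68 against -2.81) and Neurod1 (1.68 against 1.85) are close, which argues against another scale for all genes. Why Bmp4 and Steap4 differ was not tested.

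**Figure D4:**
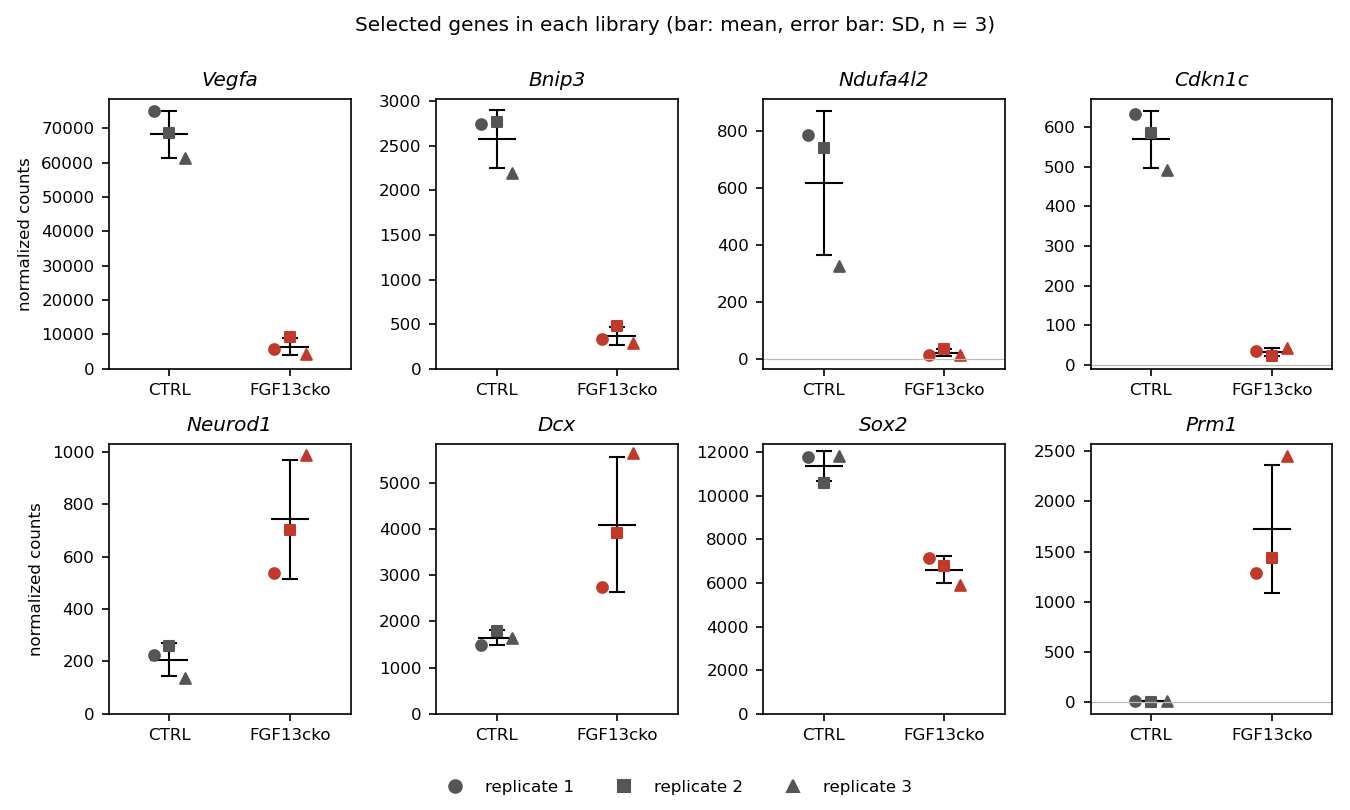
Normalized counts (vertical axis, linear) of Vegfa, Bnip3, Ndufa4l2, Cdkn1c, Neurod1, Dcx, Sox2 and Prm1 in each CTRL and FGF13cko library; symbols mark the replicate number, horizontal bars the mean and error bars the SD (n = 3). None of the 8 genes overlaps between the groups, and Prm1 stays near 6.41 in CTRL.

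The other fixed lists did not pass with the preset correlation, although single members did. Among the fits that left out 1 library, each of these counts was highest without CTRL 3. The endothelial list had 2 of 10 members higher (0 to 4 changed with 1 library left out, 6 with the replicate block; median 1.0, camera adjusted p = 0.0514; 0.0344 with the replicate block, and adjusted p = 0.743 with the block and an estimated correlation), among them Cdh5 with 5 reads in CTRL and 82 in FGF13cko, a ratio of 15.8 (95% counting interval 6.48 to 49.8). FGF/ERK feedback targets had 3 of 16 higher (0 to 7 with 1 library left out, 7 with the replicate block; median 0.43, camera adjusted p = 0.0682; 0.0344 with the replicate block, and adjusted p = 0.743 with the block and an estimated correlation), led by Fosl1, from 132 ± 32.5 to 302 ± 14.6 normalized counts, which overlaps Ccdc85b. Mural and fibroblast genes had 5 of 12 higher and 1 lower (0 to 10 changed with 1 library left out; camera adjusted p = 0.189). Ependymal and choroid plexus genes had 3 of 8 higher (1 to 4 with 1 library left out; camera adjusted p = 0.068), among them Ccdc153 with 7 reads in CTRL and 127 in FGF13cko, a ratio of 17.4 (95% counting interval 8.21 to 44.2). Intermediate progenitor and neurogenic factors moved both ways, with 3 of 16 higher and 4 lower (1 to 8 changed with 1 library left out; camera adjusted p = 0.78). In the Wnt list 4 of 19 rose and 1 fell (1 to 7 changed with 1 library left out, 9 with the replicate block; camera adjusted p = 0.0682), and Wnt8b, a ligand of the hippocampal primordium, went from 42.2 ± 12.0 to 177 ± 18.5. Adjusted over the list alone, 5 endothelial members were higher and 1 lower, 6 mural and fibroblast higher and 3 lower, 4 intermediate progenitor higher and 4 lower, 4 Wnt higher and 1 lower, 5 FGF/ERK higher and 4 ependymal higher. Fosl1 missed the threshold without FGF13cko 2 or FGF13cko 3 (limma adjusted p = 0.0665 and 0.0517), and Cdh5 without FGF13cko 1 (0.0553).

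Members of the remaining lists changed singly, and the camera adjusted p of these lists was 0.142 or more. Among all 16852 tested genes 2465 passed, and 5064 with the replicate block. Some members of any list can therefore pass, here and in the paragraph above, without a change particular to the list. Among FGF ligands and receptors 2 of 12 rose and 2 fell (2 to 7 changed with 1 library left out), and the receptor gene Fgfr3, also an astrocyte marker, fell from 6464 ± 989 to 2133 ± 264 normalized counts. Astrocyte genes had 1 of 17 higher and 2 lower (1 to 10 changed with 1 library left out, 4 higher and 4 lower with the replicate block). The stress response list had 1 of 19 higher and 7 lower (3 to 11 changed with 1 library left out, 13 with the replicate block), with asparagine synthetase (Asns) going from 3707 ± 147 to 1771 ± 83.8. Cell cycle inhibitors and p53 targets had 4 of 16 higher and 2 lower (1 to 10 changed with 1 library left out, 10 with the replicate block). BMP and TGF-beta genes had 2 of 19 higher and 3 lower (0 to 8 changed with 1 library left out, 10 with the replicate block), with the BMP inhibitor Smad6 from 78.6 ± 32.8 to 18.8 ± 2.06. Hedgehog genes had 1 of 11 higher and 1 lower, regional identity genes 1 of 19 higher and 1 lower (Nr2f1), MHC class I genes 1 of 11 higher (Nlrc5) and 1 lower, and cholesterol synthesis genes 1 of 20 lower. With 1 library left out, 0 to 5, 0 to 3, 0 to 3 and 0 to 9 members of these 4 lists changed, and with the replicate block 6, 7, 4 and 1. In the BAF chromatin remodelling complex 3 of 26 fell (0 to 7 with 1 library left out), led by Bcl7a, from 2608 ± 365 to 1505 ± 67.5. Arid1b, a BAF subunit named in advance, was at 1684 ± 337 and 1652 ± 48.5 and did not pass (log2 change -0.01, SE 0.17, limma adjusted p = 0.982). No immediate early gene of 17 passed by limma (3 with the replicate block), and neither did any of 14 X-linked neighbours of Fgf13 (1 with the block). Adjusted over the list alone, 4 FGF family members were higher and 2 lower, 2 stress response members higher and 8 lower, 6 cell cycle inhibitor members higher and 4 lower, 2 BMP members higher and 5 lower, and 2 hedgehog members higher and 3 lower. The regional identity list then had 1 lower and none higher, and the other lists of this paragraph kept their counts. Of the genes named here, Smad6 and Nlrc5 missed the threshold without FGF13cko 2 (limma adjusted p = 0.057 and 0.0572). Bcl7a and Nr2f1 missed it without CTRL 1, FGF13cko 2 or FGF13cko 3 (limma adjusted p = 0.0575 to 0.0966), and Nr2f1 also without FGF13cko 1 (0.0518).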

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

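Fits without both replicate 3 libraries, edgeR with the replicate block and the block with an estimated correlation were chosen after seeing the data. The count of changed genes (2465) stayed within 1.5 times under the other pseudocounts, filters, scalings, the robust fit, edgeR (2629) and DESeq2 (3442). With 1 library left out it ranged from 469 (without FGF13cko 2) to 4373 (without CTRL 3), with 193 to 2228 higher and 276 to 2145 lower; 2 libraries against 3 leave fewer residual degrees of freedom, and why CTRL 3 raised the count when removed was not tested. The replicate block gave 5064 genes (2723 higher, 2341 lower), all 2465 among them, and edgeR with the replicate block gave 5290 (2642 and 2648). Without both replicate 3 libraries the count was 6145 (3111 and 3034). Array quality weights gave 9559 (4748 and 4811), but the weights did not converge and ran from 0.113 for CTRL 3 to 7.59 for FGF13cko 2. A minimum change of 1.5-fold left 2323 genes. No gene past the threshold in both the main test and an alternative changed direction. Fgf13 kept its direction in all fits and passed with array quality weights (-1.09), without both replicate 3 libraries (-1.35) and among the fits leaving out 1 library only without CTRL 3 (-1.15, in a range of -1.15 to -0.53); the cause was not tested. The count of lists (12) was 19 without the filter on low values, where more low members count, and 11 to 18 in the other fits with a preset correlation. It was 0 with an estimated correlation, with or without the replicate block (lowest adjusted p = 0.638), and a list test on DESeq2's fit was not run. All 12 lists kept their call with each library left out, and 11 of 11 testable did with a minimum mean of 50. Arid1b, near 0 in the main test (-0.01), turned above 0 with libraries scaled to the same total (0.0055) and without CTRL 1 (0.098), CTRL 2 (0.065), FGF13cko 1 (0.0050) or FGF13cko 3 (0.0051), and ran down to -0.18 without CTRL 3, none of them past the threshold; the cause was not tested. Of 60 named genes past the threshold, 30 kept it with each library left out and 30 missed it at least once, without FGF13cko 2 most often (28 genes); Cdh5 and Oas1a were tested in 5 of these 6 fits. The replicate block brought Nes and Mki67 past the threshold, the mitochondrially encoded, endothelial and FGF/ERK feedback lists past theirs, and changed the call of no other named gene or fixed list. Depth was similar in all libraries (22191718 to 24531400 reads), and it limits genes with a few reads in CTRL, such as Oas1a, Scn4b, Cdh5 and Ccdc153, whose ratios span wide intervals.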

Other observations

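All tests reported in this part were chosen only after the result was seen, except the scaling test and the second list for the hypoxia genes and the count over other splits of the libraries.

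Imprinted genes, which are expressed from 1 parental copy, moved in both directions. H19, a maternally expressed noncoding RNA, went from 678 ± 23.1 normalized counts in CTRL to 53.7 ± 14.6 in FGF13cko (SD, n = 3 each; log2 change -3.67, SE 0.23, limma adjusted p = 0.00115), alongside the fall of Cdkn1c given above. Igf2, its neighbour, was at 5.06 ± 1.0 and 4.54 ± 2.44. In a further list of imprinted genes that leaves out H19 and Cdkn1c, 7 of 25 tested members passed, 6 higher and 1 lower. Grb10, an adaptor that restrains growth factor signalling, fell from 4715 ± 983 to 1496 ± 457. Mirg, of the Dlk1-Dio3 cluster, rose from 20.2 ± 2.77 to 76.3 ± 28.7, Plagl1 from 230 ± 25.6 to 448 ± 56.4, Peg13 from 734 ± 126 to 1396 ± 84.8 and Impact from 1017 ± 75.7 to 1646 ± 56.9. Against 14.6% of other genes past the threshold, the odds ratio of 2.27 (95% interval 0.802 to 5.71) did not pass Fisher's exact test, 2-sided (p = 0.0811). With the replicate block 13 of 25 passed, 11 higher and 2 lower, against 30.0% of other genes (odds ratio 2.53, Fisher's exact p = 0.0265). Fisher's test counts genes as independent. Meg3, Rian and Mirg share a cluster and passed together with the block (limma adjusted p = 0.0239, 0.00133 and 0.00432), so its p can be too small.

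The count of 2465 changed genes was the highest of the 10 ways to split the 6 libraries into 3 and 3, reached by 1 split, the real one, and the highest of the others gave 0. The 10 splits are too few for a share under 0.05. Each of the other splits also puts both genotypes into each group, which widens the spread within groups, so few calls were bound to follow there. Among the 4 splits that part every same-numbered pair, the replicate block gave 5064 genes in the real one and 0 in each of the others, which mix the genotypes within both groups.

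Prm1 was near background in all 3 CTRL libraries and at 1284, 1431 and 2453 normalized counts in FGF13cko 1, 2 and 3. A germ cell programme is argued against, since 0 of 10 other spermatid genes reached a mean of 10 in FGF13cko, Prm2 and Tnp1 being at 0 in every library. A candidate explanation is transcribed Prm1 sequence in a construct, as hGFAP-Cre transgenes in common use carry the end of mouse Prm1, and 0 of 4 tested genes within 100 kb of Prm1 rose. Both groups are labelled as carrying hGFAPCre, and a ratio of 269 in Prm1 reads goes against the same construct being active alike in both, so the labels and this explanation may not both hold as written. Which construct the mice carried, whether the CTRL libraries express Cre, and any effect of Cre itself on the other changed genes were not tested.

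The fall of the hypoxia and glycolysis list was tested against the scaling of the libraries, and its median stayed at -1.30 or lower under 3 other scalings, so scaling does not account for it. A second list of HIF targets without members of the first had 18 of 27 tested genes lower past the threshold and none higher. This second list was not among the 35 fixed lists. It holds targets of the same pathway measured in the same 6 libraries, so it is not separate evidence. Its median was -1.23 (-1.20, -1.11 and -1.39 in FGF13cko 1, 2 and 3). The camera p was 5.34e-14, and p = 0.0553 with an estimated correlation, which does not pass. Pfkfb4 went from 203 ± 11.4 to 282 ± 35.3 normalized counts and Cited2 from 717 ± 44.0 to 908 ± 163, higher without passing. The direction of the members that fell would go with a lower activity of the oxygen-sensing HIF pathway in the FGF13cko cultures. An effect of the genotype and a difference in oxygen, density or sphere size between cultures cannot be told apart, because each culture holds 1 genotype and no oxygen or sphere measure was used here.

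The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were lower in CTRL 2, at 0.47, 0.43, 0.46 and 0.41 of their values in CTRL 1 (95% counting intervals between 0.37 and 0.51). Female cells in that library are argued against, since Xist was at 5.03 normalized counts there and at up to 13.2 in the others. Depth or scaling is argued against by the X-linked homologues, whose median ratio was 1.03. A Y chromosome missing from part of the cells of CTRL 2 would lower the 4 genes alike, but how even the fall was depended on the library compared. The ratios of CTRL 2 differed between the 4 genes by 1.13 times against CTRL 1, 1.42 against CTRL 3 and 1.78, 1.51 and 1.53 against FGF13cko 1, 2 and 3. The uneven ratios do not exclude this explanation either, since CTRL 1 and CTRL 3 differed from the FGF13cko libraries by 1.56 to 2.04 times on the same measure, so it stays open. None of the 4 genes passed the test between the genotypes (limma adjusted p = 0.46 to 0.96).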
